A study of Schizosaccharomyces pombe with 16 samples.

How the data were processed

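The samples were 16 ChIP-chip arrays of Schizosaccharomyces pombe cells in synchronous meiosis. Per the labels, cells were starved of nitrogen, and meiosis was then started by a shift in temperature with nitrogen added. Proteins were crosslinked with formaldehyde and pulled down through a GFP or FLAG tag, and the break maps used FLAG-tagged Rec12 without a crosslinker. Recovered DNA and input DNA were amplified, labelled with Cy3 or Cy5 and hybridized together, per the labels. The deposited scanner files give processed signals as intensity values, which Agilent Feature Extraction (version 10.5.1.1 for 5 arrays and 10.7.3.1 for 11) had background-subtracted and dye-normalized within each array, per the file headers. The same files hold the mean signal and the local background median of each spot as scanned, also intensity, per the file headers. The deposited series matrix holds log10 ratios; comparison with the scanner files showed that its columns are red over green, centred on the array median and with the sign turned on the Rec10 array. No step between these files is stated in the labels. Dye normalization and median centring fix the middle of each array, so values show enrichment relative to the rest of that array and no difference in total binding.

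From the processed signals the log2 ratio of immunoprecipitate over input was computed per spot and spots carrying the outlier flag of Feature Extraction were left out, between 0.0183% of probes (Rec27 in the rec12 deletion) and 19.1% (Rec25 replicate 1). The median of each array was then subtracted. The array was designed on an older build, so the probe sequences were matched to the reference ASM294v3. Of 43832 probes 42917 had 1 exact match, 908 had several and 7 had none. Only single matches were used, except in the separate count of centromere probes. All coordinates are on ASM294v3, and gene names come from its annotation. Windows of 1 kb with at least 2 probes were averaged (10451 windows). Sites were called per group as runs of at least 3 probes whose running mean over 500 bp to each side exceeded the array median by 4 null SDs, with gaps of up to 1 kb joined. The null SD was estimated from values below the median. Site heights are the highest running mean, and values at sites are means over the probes of a site.

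Groups were taken from the labels. limma 3.58.1 (R 4.3.3) was fitted to the windows of the 6 GFP arrays of Rec27 and Rec25, with Benjamini-Hochberg adjusted p under 0.05 and 2 residual degrees of freedom, which come from the pairs of Rec27 and Rec25 replicates. The lone rec12 and rec8 deletion arrays were assumed to vary like these, so their SE and p do not cover variation between deletion samples. Comparisons of 1 array with 1 array were given no p. Their median over Rec27 sites was set beside 10000 random site sets of the same number and probe counts, overlaps were set beside 1000 rotations of the sites along the genome, and region medians beside 10000 rotations (1000 for regions of more than 2000 probes). Gene list medians were set beside 10000 random lists of the same size. Percentiles describe these arrays alone. Intervals of shares are Wilson 95% intervals. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9.

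The genes named in the text were fixed by a rule. They were the deleted genes, the 10 highest Rec27 sites, the 10 runs of windows with the largest difference each way per limma comparison (with both replicates on the same side of the lone array), the 5 sites with the largest difference each way per comparison of single arrays, the 5 highest sites of each other group, and up to 4 members of each gene list with the largest absolute value. A window or site was named by the gene it overlaps or else by its neighbours. The lists were genes of meiotic recombination and linear elements, cohesin, meiotic entry, middle meiosis, glycolysis and high transcription, histones, stress response, nitrogen starvation, strain markers, the mitotic cell cycle and ribosomal proteins. Regions were coding genes, intergenic regions by orientation and length, tRNA genes outside centromeres, centromeres, chromosome ends and the mating type region. These lists, the comparisons and their tests were chosen before the data were examined, but most tests of explanations for single patterns were not. The mat1 cassette genes had no probe or no entry in the annotation used.

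The plan was departed from in 1 respect. It called Rec27 sites from the mean of both replicates, but these ran opposite to each other and their mean cancels, so replicate 1 alone defined the 158 sites used throughout, and the other choices are given beside it. That choice, the reading of Rec27 replicate 2 as turned, the crossed pairing, the replicate block combined with the GC trend, Rec25 sites as reference and outlier flags on the input signals were added after seeing the data. Alternatives fixed beforehand were normexp background correction (offset 50), the series matrix values, division of each array by its null SD, quantile normalization, no filter on outlier flags, a filter on dim input probes, removal of the GC trend, windows of 500 bp and 2 kb, a minimum log2 difference of 0.5, sites at 6 null SDs or as the top 3% of probes, summits within 1 kb as overlap, Spearman correlation, other chromosome end widths, the replicate block, all 16 arrays in the fit, the Rec10 sign turned and each replicate left out.

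The steps were tested on simulated data. Windows were shifted in arrays simulated at the spread of the reading with Rec27 replicate 2 turned. There limma recovered 77.6% of shifts of 1 (log2) for Rec27 against Rec25, 71.6% for the rec12 deletion and 70.1% for the rec8 deletion. It recovered 100% of shifts of 2 in each, with 6, 6 and 8 false calls among 10451 windows. For shifts of 0.5 it recovered 8.96%, 1.49% and 11.9%. The spread as labelled was not simulated, so these shares do not apply to the counts of windows as labelled. Site calling found 50 of 50 planted sites at heights of 1.5 and 3, 17 of 50 at 0.8 and 0 where none were planted. That noise was drawn independently for each probe at a single spread. Real null SDs ran from 0.14 (Rec27 in the rec12 deletion) to 0.81 (rec10-109 breaks, site threshold 3.20). These shares therefore do not apply to each array, and the rate of false sites on the real arrays was not measured. Of 50 random site sets without signal, 46 fell within the central 95% of theirs.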

Results

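The series mapped proteins of meiotic recombination along the chromosomes of fission yeast (Schizosaccharomyces pombe) by chromatin immunoprecipitation on tiling microarrays (ChIP-chip). Each of 16 Agilent 2-colour arrays set immunoprecipitated DNA against input DNA, and values are given as log2 ratios of immunoprecipitated over input. The arrays fell into 14 groups. Rec27 and Rec25, components of the linear elements that fission yeast forms along its meiotic chromosomes in place of a synaptonemal complex, had 2 wild-type arrays each. The other 12 groups had 1 array each and thus no replicates. They held the linear element proteins Mug20 and Rec10, the meiotic cohesin subunits Rec8 and Rec11, and Rec12, the Spo11 ortholog that makes meiotic DNA breaks. Rec27 was also mapped in a rec12 deletion and in a rec8 deletion, and Rec12 in a rec27 deletion. Rec12-Y98F, in which the active-site tyrosine was replaced, was mapped at 3 h and 4 h. A pair of arrays mapped the breaks themselves, as DNA bound covalently to Rec12 without crosslinking, in strains labelled rec11 deletion (9 h) and rec10-109 (11 h). The remaining arrays came from 3.5 h of meiosis. Each array carried 43832 probes, of which 42917 matched a single place in the reference genome, at a median spacing of 264 bp. Median processed signals per array lay between 991 and 1363 in Cy3 and between 1005 and 1334 in Cy5. On each array 0 to 228 probes per channel were not well above background and 0 were saturated. The small number of arrays limits the precision of every value below, and spreads and p-values describe only these arrays, since nothing in the labels says that replicates came from separate cultures.

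The deleted genes were read first, from the input DNA over each gene against the same probes on the other arrays. The rec8 gene (II, 2568938 to 2570993, reference build ASM294v3, 7 probes) was lower by a log2 difference of -11.56 on the array labelled rec8 deletion. The rec12 gene (I, 1772925 to 1774203, 4 probes) stood at -10.39 in the rec12 deletion. The rec27 gene (II, 757399 to 758042, 2 probes) stood at -10.64 in the rec27 deletion. The size of these losses depends on how background is handled and is not exact. The rec11 gene (III, 1223308 to 1226968, 14 probes) was present on the array labelled rec11 deletion, with an input difference of -0.05. On the other arrays it lay between -0.21 and 0.12, so the DNA did not bear out that label, and the array is called "labelled rec11 deletion" throughout. The rec10 gene (I, 4301367 to 4303893, 9 probes) stood at -0.04 in rec10-109, a mutant allele that need not remove DNA. Among the strain markers, ade6, an adenine biosynthesis gene used as a recombination reporter, had a difference of 3.54 in the channel labelled input on Rec27 replicate 2, an array whose direction is not settled, so this value cannot be read as a difference in DNA. On the other arrays ade6 input lay between -0.95 and 0.93.

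Rec25, Rec27, Mug20 and Rec12 shared much of their profile along the chromosomes, and the cohesin subunits correlated most with each other. Across 10451 windows of 1 kb the Rec25 replicates correlated at r = 0.915. Rec27 replicate 1 correlated with Mug20 at 0.75 and with the Rec25 arrays at 0.66 and 0.69. Rec8 and Rec11 correlated with each other at 0.745, while Rec8 stood at 0.19 to 0.22 with Rec25, 0.389 with Rec12 and 0.437 with Mug20. Mug20 with Rec11 gave 0.453, and by Spearman rank correlation 0.587, above Mug20 with Rec25 (0.571 and 0.550). Rec12 followed Mug20 at 0.70 and Rec25 at 0.62. Windows are neighbours on the same DNA and are not independent replicates, so no test was applied to these values.

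Rec27 replicate 2 ran opposite to the rest and has no settled direction. Its r with Rec27 replicate 1 was -0.70, with Rec27 in the rec12 deletion -0.91 and with the Rec25 arrays -0.82 each. Read with immunoprecipitate and input exchanged ("turned"), it correlated with replicate 1 at 0.695. Its labels put the immunoprecipitate in Cy5, but the Cy5 channel followed the pooled input of the other arrays more closely (r = 0.791) than the Cy3 channel did (r = 0.535). Results that use it are therefore given as labelled, turned and without it. The Rec10 array has labels that contradict each other on the dyes. Its description was followed (immunoprecipitate in Cy3), and Rec10 comparisons are given with the sign turned as well.

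**Figure D1:**
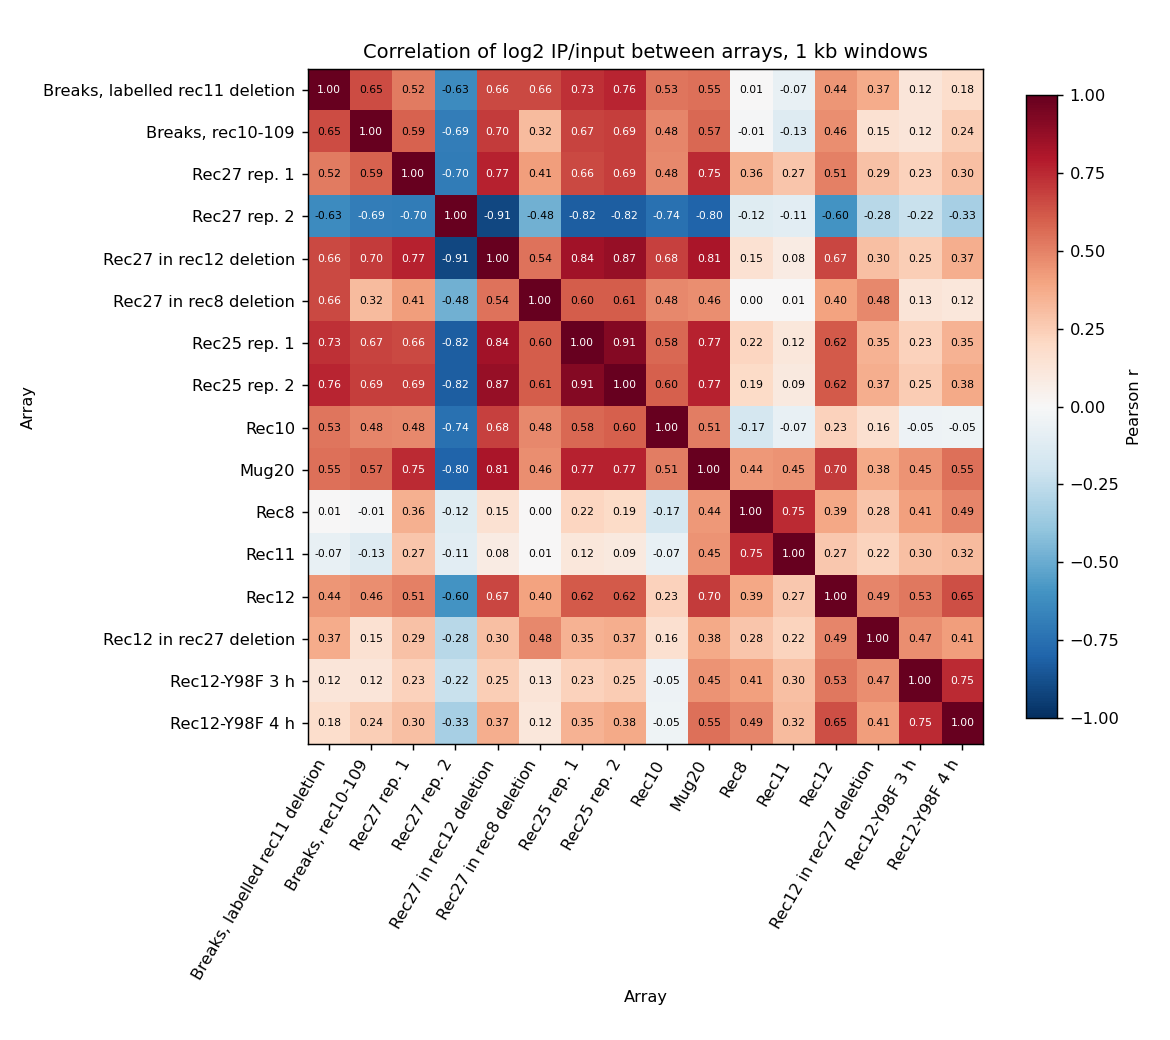
Pearson r of log2 immunoprecipitate over input between each pair of the 16 arrays across 10451 windows of 1 kb; both axes list the arrays and the colour and the printed value give r. Rec27 replicate 2, as labelled, is negative with each other array, down to -0.91 with Rec27 in the rec12 deletion, and the Rec25 replicates stand at 0.915.

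Rec27 replicate 1 bound 158 sites with a median width of 1551 bp, which together covered 287 kb. Chromosome I held 73 of them, chromosome II 45 and chromosome III 40. The highest lay upstream of ste11, which encodes the transcription factor that starts mating and meiosis (between cyc3 and ste11; II, 3979683 to 3983744; height 3.89). The next were between peg1 and pdc201, the latter a pyruvate decarboxylase gene (I, 3157958 to 3160107; 3.75), and between ptr2, a peptide transporter gene, and ptk1 (II, 3407990 to 3409982; 3.73). Further high sites lay between SPBC1685.17 and fhn1, which encodes an eisosome protein (II, 522689 to 526127; 3.67), and between SPAPB15E9.02c and SPAPB15E9.06 (I, 3990974 to 3995251; 3.65). The site between gap1, a regulator of Ras, and sds23 (II, 948535 to 951061) reached 3.41, as did that between pan3 and bsu1 (I, 3548212 to 3551493). The site between eme1, a subunit of the Mus81 endonuclease, and glt1 (I, 3300665 to 3303331) reached 3.36. The last of the 10 highest were beside lsd90 (II, 1951214 to 1952619; 3.35) and between the kinesin gene klp9 and gsf1 (II, 3008658 to 3012392; 3.33). Rec27 sites lay mostly between genes. Of their summits 95 of 158 (60.1%, 95% Wilson interval 52.3 to 67.4) fell in intergenic regions of the longest class, 1906 bp or more, which held 12.2% of the probes, and 17 summits lay in coding DNA. With both replicates averaged as labelled 33 sites were called, with replicate 2 turned and averaged 294, and from replicate 2 alone 0 as labelled and 339 turned.

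**Figure D2:**
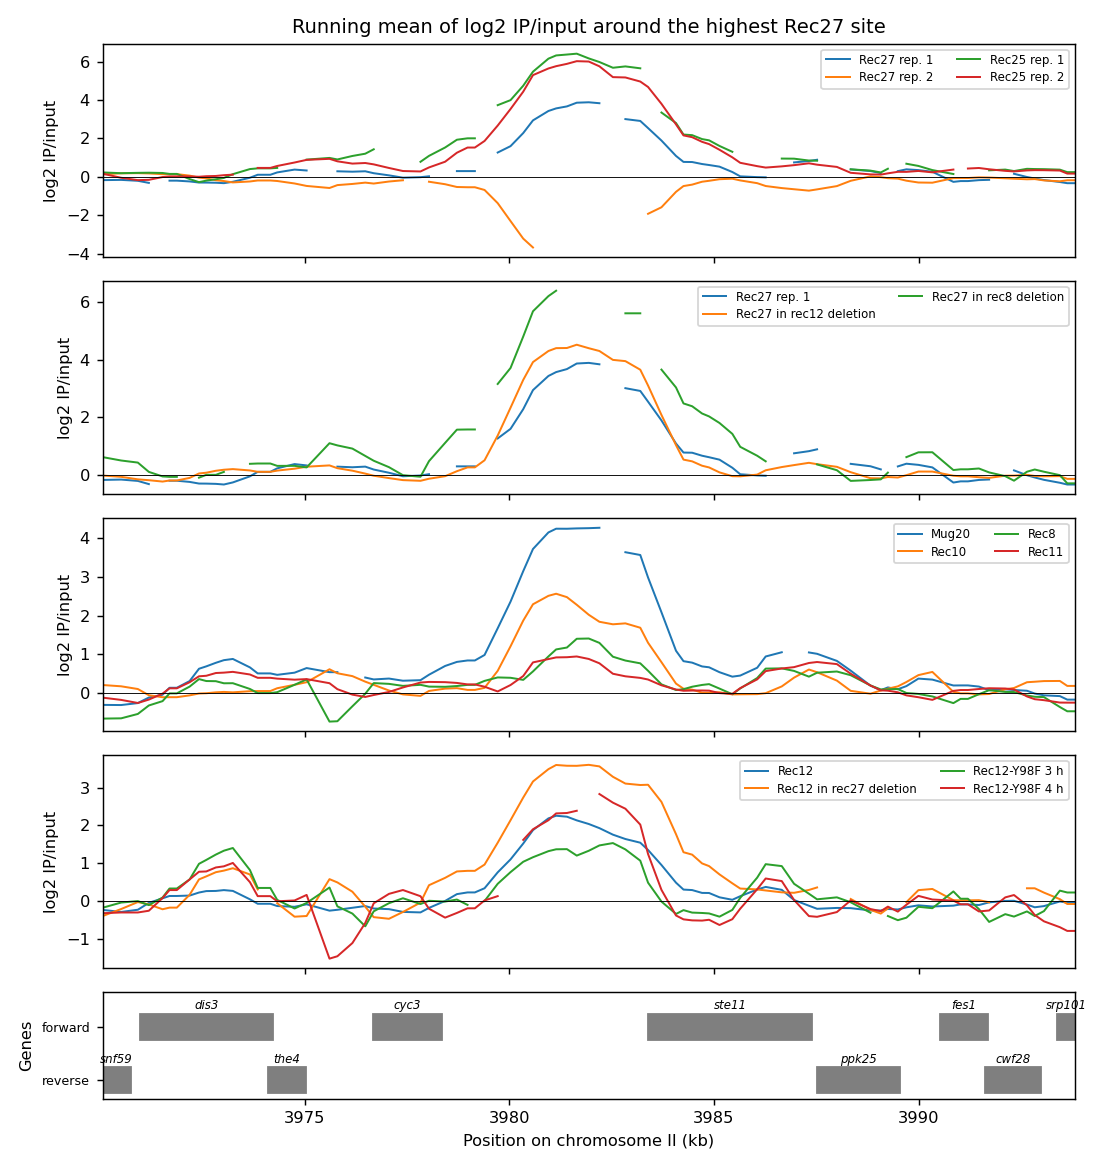
Running mean of log2 immunoprecipitate over input (y axis) along chromosome II in kb (x axis) around the highest Rec27 site, in 4 panels of arrays, with annotated genes below. Gaps lie at probes left out by the spot filter. The peak between cyc3 and ste11 is seen for Rec27 replicate 1 (3.89), Rec25, Mug20 (4.26) and Rec10 (2.56), and Rec27 replicate 2 as labelled is negative on both flanks (-3.68 and -1.93), with most of its spots at the peak filtered out and a lone value of 0.77 at the summit that is not drawn.

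The linear element proteins shared these sites, and the cohesin subunits had lower medians there. Median log2 ratios over the 158 sites were 2.74 and 2.36 on the Rec25 replicates, 1.82 for Mug20 and 0.71 for Rec10 (-0.71 with the sign turned), beside 1.85 for Rec27 replicate 1 itself. Rec27 replicate 2 stood at -1.79 as labelled and 1.79 turned. Rec8 had a median of 0.26 and Rec11 of 0.05. The medians of Rec25, Mug20, Rec10 and Rec8 lay above those of 10000 random site sets of matched size, and that of Rec11 at percentile 97.4. Over the 255 Rec25 sites instead, Rec8 had a median of 0.05 and Rec11 of -0.10, below its random site sets. Rec25 sites overlapped 128 of the 158 Rec27 sites (81.0%, Wilson interval 74.2 to 86.4), where rotation of the site set along the genome gave 14 in the median. Mug20 overlapped 107 (67.7%) and Rec10 86 (54.4%), against 7 and 5 by rotation, and Rec10 turned had 0 sites. Rec8 overlapped 2 and Rec11 overlapped 5, but only 12 Rec8 and 27 Rec11 sites were called, so these overlaps could not be large. Rec8 was above 0 at 117 of the 158 sites and Rec11 at 88. Each linear element protein peaked at ste11, with heights of 6.23 for Rec25, 4.26 for Mug20 and 2.56 for Rec10 (-2.56 turned). The highest Rec25 site lay between rps1801 and mbx2, the latter a MADS-box transcription factor gene (II, 3620992 to 3633767; 6.32). Mug20 was higher than Rec10 at 153 of the sites, by a median of 1.07, with the widest gap between gpa2, a G protein subunit gene, and avl9 (2.72). At the site between mei2, a regulator of meiotic entry, and omt2 (I, 4515262 to 4516391) Mug20 was lower than Rec10 by -1.26. With the Rec10 sign turned Mug20 was higher at 156 sites, by a median of 2.74, and the differences beside gpa2 and mei2 were 5.63 and 1.33. Rec8 exceeded Rec11 at 121 of the 158 sites, by a median of 0.18, most between clg1 and scr1 (0.93) and near fba1 (0.89), and was lower between ddr48 and jmj1 (-0.78). A comparison of single arrays has no replicate check.

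**Figure D3:**
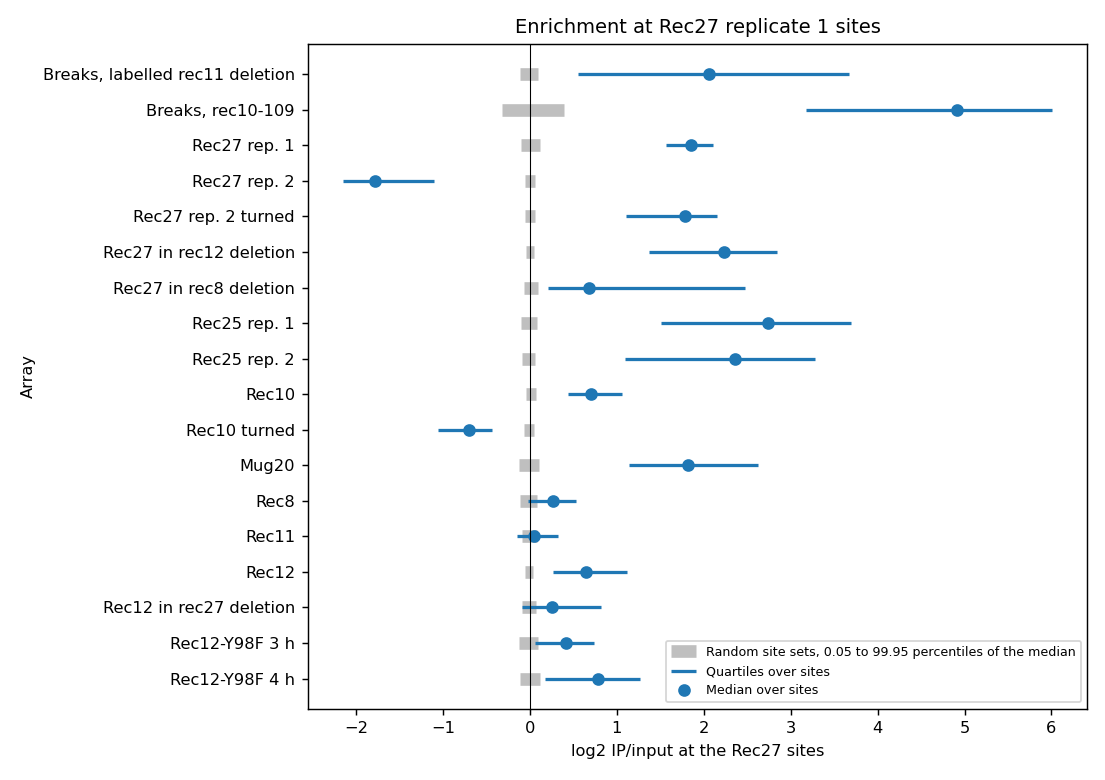
Log2 immunoprecipitate over input (x axis) at the 158 Rec27 replicate 1 sites for each array (y axis), with Rec27 replicate 2 and Rec10 also shown turned; points are medians over sites, lines the quartiles and grey bars the range of random site sets. Rec25 stands at 2.74 and 2.36, Mug20 at 1.82, and Rec11 at 0.05 lies within its grey bar.

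Rec27 and Rec25 were compared to ask whether the pair of linear element proteins differed anywhere in the genome. Because the Rec27 replicates ran opposite, the fit as labelled had a wide spread and its count is no evidence of equal binding. As labelled, limma called 0 of 10451 windows at an adjusted p under 0.05 (802 at an unadjusted p under 0.05, smallest adjusted p 0.646, 2 arrays against 2). With Rec27 replicate 2 turned it called 321, 23 higher for Rec27 and 298 lower, and without that replicate 522, 161 higher and 361 lower. The windows called in the same direction in both of the last readings numbered 292. With replicate 2 turned, Rec27 was higher at its own tagged locus, between tho5 and rec27 (II, 757001 to 758000; log2 difference 2.02 ± 0.20 SE, limma adjusted p = 8.63e-06). It was also higher beside the invertase gene inv1 (III, 1723001 to 1724000; 1.34 ± 0.30) and near frg1 (1.26), the flocculin gene gsf2 (1.13) and the alcohol dehydrogenase gene adh8 (0.96). It was lower between SPAC5H10.07 and pan6, a pantothenate synthesis gene (I, 159001 to 160000; -4.16 ± 0.22, limma adjusted p = 7.94e-09), and downstream of mbx2 (II, 3629001 to 3630000; -3.18 ± 0.26). Further windows with lower Rec27 lay between gpa2 and avl9 (I, 2519001 to 2520000; -2.80 ± 0.39), near fhn1 (-2.79), between pcs2 and hsr1 (I, 1955001 to 1956000; -2.71 ± 0.23) and between cyc3 and ste11 (II, 3983001 to 3984000; -2.61 ± 0.23). Windows near the hexokinase gene hxk2 (-2.65), txc1 (-2.61), puf5 (-2.60) and esc1 (-2.57) completed the 10 largest. Of the 336 windows in Rec27 sites, 4 had higher Rec27 and 126 lower, and without replicate 2 these were 31 and 128. The 739 windows in Rec25 sites gave 0 and 291, but choosing sites by Rec25 favours that direction. In the turned reading limma called 0 windows after normexp background correction and 0 after division by the null SD, and quantile normalization left 5, 1 higher and 4 lower.

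Rec27 kept its sites in the rec12 deletion, where breaks cannot form. The rec12 deletion array had 317 sites, which overlapped 147 of the 158 wild-type sites (93.0%, Wilson interval 88.0 to 96.1, 16 by rotation), but its sites were called above 0.56 and those of replicate 1 above 1.23, so the overlap alone does not show equal binding. Its median over the sites was 2.24, higher than Rec27 replicate 1 by a median of 0.30, an increment within the 0.37 by which the Rec25 replicates differed, and quantile normalization turned it to -0.14. On the slide that held both arrays, the rec12 deletion exceeded Rec27 replicate 2 by 4.07 as labelled and by 0.375 with that replicate turned. Its highest sites lay between cyc3 and ste11 (4.52, against 3.89 on replicate 1), between rps1801 and mbx2 (4.43 against 2.91) and between klp9 and gsf1 (4.37 against 3.33). In the limma fit as labelled, the opposed wild-type replicates cancelled in the mean and widened the spread. A count of 0 from that fit is no evidence that Rec27 was unchanged. limma, which took the spread of the lone deletion array from the Rec27 and Rec25 pairs, called 0 windows as labelled (60 at an unadjusted p under 0.05) and 0 with replicate 2 turned (140, smallest adjusted p 0.453). Without replicate 2 it called 12, each higher in the deletion. The 12 included windows between gpa2 and avl9 (I, 2519001 to 2520000; 2.69 ± 0.32 SE, limma adjusted p = 0.0038), beside wis1, a stress-activated MAP kinase kinase gene (1.96 ± 0.28), near mug14 (1.94), txc1 (1.94) and pat1, the kinase gene that holds cells out of meiosis (1.92). The gpa2 window stood at 1.17 on replicate 1, 3.01 on replicate 2 turned and 3.86 in the deletion, so these 12 calls depend on which array is left out. In the turned reading 4 windows were called without Rec27 replicate 1 and 15 without either Rec25 replicate, each higher in the deletion.

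Without Rec8, Rec27 signal was low at most of its sites on chromosome III and remained at a part of those on chromosomes I and II. The rec8 deletion array had 94 sites, 48 on chromosome I, 40 on II and 6 on III. They overlapped 33 of 73 wild-type sites on chromosome I (45.2%), 18 of 45 on II (40.0%) and 6 of 40 on III (15.0%, Wilson interval 7.06 to 29.1), 57 of 158 in all. Median log2 ratios at the sites were 0.96 on chromosome I, 0.99 on II and 0.12 on III, where Rec27 replicate 1, which defined the sites, had 1.79, 1.95 and 1.72. Other wild-type arrays also stood lower on III than on I and II together, with 1.17 against 1.86 on Rec27 replicate 2 turned (-1.17 and -1.86 as labelled) and 1.49 against 2.98 and 1.01 against 2.52 on Rec25, so the gap was not particular to the deletion. Of Rec25 sites, the deletion overlapped 41 of 119 on I (34.5%), 32 of 91 on II (35.2%) and 6 of 45 on III (13.3%). Over all sites the deletion stood lower than replicate 1 by a median of -0.97 and than replicate 2 turned by -0.62. Over the 33 sites called from both replicates averaged as labelled it stood higher than replicate 1 by 0.41. Those sites are left where the opposed replicates did not cancel, so they are not a fair sample of Rec27 sites. The highest mean was 3.67 both as labelled and with replicate 2 turned, so replicate 1 alone set it. In the limma fit as labelled the opposed Rec27 replicates widened the spread, so its count is no evidence that Rec27 was unchanged. As labelled, limma called 0 windows (501 at an unadjusted p under 0.05, smallest adjusted p 0.883, 1 array against 2). The SE and p take their spread from the Rec27 and Rec25 pairs and do not cover variation between rec8 deletion cultures. With replicate 2 turned it called 481, 189 higher and 292 lower in the deletion, and without that replicate 704, 278 higher and 426 lower. The 2 readings shared 410 windows called in the same direction. With replicate 2 turned, Rec27 was lower at ade6 (III, 1316001 to 1317000; log2 difference -2.99 ± 0.27 SE, limma adjusted p = 7.85e-06) and beside isp7, a gene induced in sexual development (I, 4178001 to 4179000; -2.82 ± 0.28). It was lower between the desaturase gene ole1 and gst4 (III, 1396001 to 1397000; -2.75), near coa6 (-2.70), between oca2 and gnr1 (-2.65), beside the iron transport genes fip1 and fio1 (-2.58) and at adh1, the main alcohol dehydrogenase gene (-2.43). The remaining windows of the 10 with the largest deficit lay near gpd3 (-2.43), dom34 (-2.25) and gsf2 (-2.24). As ade6 is a strain marker, its difference cannot be laid to the rec8 deletion alone. Rec27 was higher beside the deleted rec8 locus itself (II, 2568001 to 2569000; 3.45 ± 0.28). It was also higher between SPBPB2B2.06c and SPBPB2B2.07c (II, 4471001 to 4472000; 3.24 ± 0.33, limma adjusted p = 2.30e-05), at pan6 (3.20 ± 0.27) and between pcs2 and hsr1 (I, 1952001 to 1953000; 3.12 ± 0.28). Further windows with higher signal lay at SPAPB15E9.02c (3.11), at the phosphate transporter gene pho84 (II, 4442001 to 4443000; 2.95 ± 0.26), near the hexose transporter gene ght3 (2.90), near mug14 (2.77), between cyc3 and ste11 (2.76) and at tgd1 (2.59). Among the windows in Rec27 sites, 2 of 81 on chromosome III were higher and 41 lower, against 28 and 46 of 160 on I and 12 and 29 of 95 on II. Normexp background correction and division by the null SD left 0 windows in the turned reading, and quantile normalization left 381, 150 higher and 231 lower. Outlier flags were high on this array (18.5% of probes) and on Rec25 replicate 1, which shared its slide (19.1%).

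**Figure D4:**
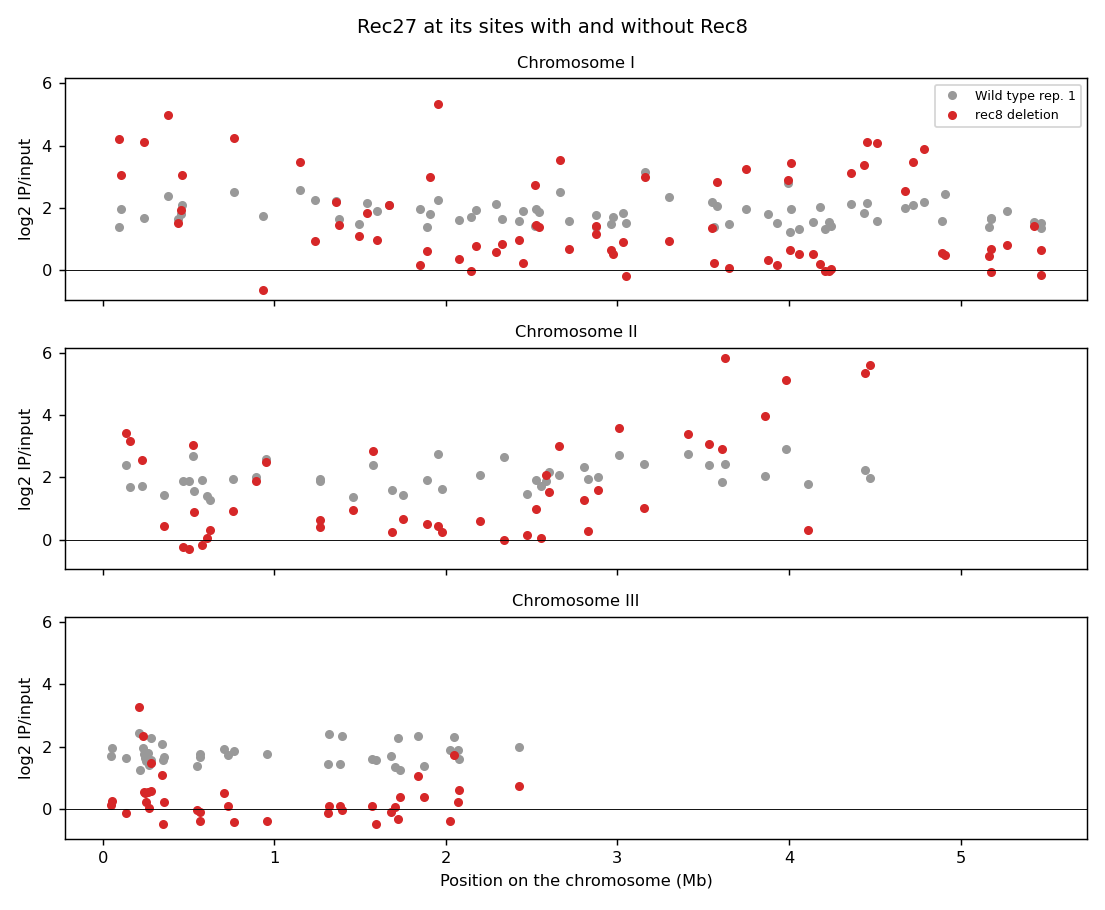
Log2 immunoprecipitate over input (y axis) at each of the 158 Rec27 sites by position in Mb (x axis) on the 3 chromosomes; grey points are Rec27 replicate 1 and red points Rec27 in the rec8 deletion. Medians of the red points are 0.96 on chromosome I, 0.99 on II and 0.12 on III.

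Rec12 occupied Rec27 sites in the wild type, and the single array from the rec27 deletion had a lower median there. The Rec12 array had 131 sites, the highest at nmt1, a thiamine-repressed gene (III, 1836852 to 1840287; 2.87), between pan3 and bsu1 (2.87), between peg1 and pdc201 (2.75) and at ade6 (III, 1315923 to 1319222; 2.66). They overlapped 86 of the 158 Rec27 sites (54.4%, 6 by rotation). In the rec27 deletion 61 Rec12 sites overlapped 35 (22.2%), but sites were called above 1.25 there and above 0.68 in the wild type, so these counts do not measure a loss. The median over Rec27 sites was 0.65 in the wild type and 0.25 in the deletion, a median difference of -0.33 per site, below the range of random site sets (-0.07 to 0.08), with 105 sites lower and 53 higher. The largest deficits lay beside lsd90 (-2.15), ptl2 (-1.90), mae1, a malate permease gene (-1.86), and at ade6 (-1.84), where Rec12 stood at 2.06 in the wild type and 0.22 in the deletion. The ade6 gene is a strain marker, so its difference cannot be laid to the rec27 deletion alone. Rec12 was higher in the deletion between SPBPB2B2.06c and SPBPB2B2.07c (3.37 against 0.27), at pho84 (by 2.61), between pcs2 and hsr1 (I, 1952165 to 1957872; 2.24), between mei2 and omt2 (2.09) and near isp3, a spore wall gene (1.58). Each of these comparisons set 1 array against 1 and has no replicate check. The median difference of -0.33 was no larger in size than the 0.37 by which the Rec25 replicates differed at the same sites. Arrays divided by their null SD gave -0.84, and over sites called from both Rec27 replicates averaged as labelled the difference was -0.01. The opposed replicates cancel in that mean, so the sites it leaves are not a fair sample of Rec27 sites.

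Rec12-Y98F, which cannot cut DNA, was found at Rec27 sites at both times, with a higher median on the single 4 h array. Medians over the 158 sites were 0.41 at 3 h and 0.79 at 4 h, both above 10000 random site sets, beside 0.65 for wild-type Rec12 at 3.5 h. The size depended on the sites used, with 0.28 at 3 h and 0.54 at 4 h over the 255 Rec25 sites. The 4 h array exceeded the 3 h array at 127 sites and by a median of 0.39. The largest gains were between gti1, a regulator of gluconate uptake, and loc1 (I, 380872 to 383310; 1.20), near sec18 (1.12), at mug116 (1.02) and beside mam1, which encodes the exporter of M-factor pheromone (1.01). Between mei2 and omt2 the 4 h array was lower by -1.08 and between meu10 and cbf12 by -0.81. Against wild-type Rec12 the 3 h array was lower at 122 of the sites, by a median of -0.35, most at ptl2 (-1.28), dom34 (-1.27), mae1 (-1.19), pil1 (-1.18) and pdc201 (-1.15). It was higher between mei2 and omt2 (0.97) and at gas2 (0.72). The 4 h array differed from wild-type Rec12 by a median of 0.02, within the range of random site sets (-0.09 to 0.10), with gains at puf5 (1.25), gti1 (1.18) and the enolase gene eno101 (1.04) and deficits at the sterol synthesis gene erg31 (-0.93), gud1 (-0.81) and dom34 (-0.78). Called sites were few, with thresholds of 1.67 and 1.72 against 0.68 for wild-type Rec12, 19 at 3 h, led by the interval between mei2 and omt2 (I, 4515850 to 4517242; 3.23), and 33 at 4 h, led by nmt1 (III, 1837725 to 1839627; 3.71) and ade6 (3.46). Times differed between the arrays compared, and each comparison had 1 array per side. The Rec25 replicates differed by a median of 0.37 at the same 158 sites. The medians of 0.39 and -0.35 between single arrays were close to that in size.

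Breaks in both maps were seen at most Rec27 sites. The map labelled rec11 deletion had 160 sites, which overlapped 100 of the 158 Rec27 sites (63.3%, 12 by rotation). The rec10-109 map had 249, which overlapped 119 (75.3%, 15 by rotation). Of the break sites themselves, 102 of 160 (63.8%) and 123 of 249 (49.4%) overlapped a Rec27 site. The highest break site in both was upstream of ste11 (II, 3980307 to 3990366 with height 7.01, and 3978398 to 3985476 with height 8.08). In the map labelled rec11 deletion the next were between pcs2 and hsr1 (6.56), klp9 and gsf1 (6.48), gti1 and loc1 (6.42) and ecl3 and pho84 (6.01). In rec10-109 they were between peg1 and pdc201, between sul1, a sulfate transporter gene, and spo14 (7.90), at mug115 (7.70) and at pho842 (7.58). Median log2 ratios over the Rec27 sites were 2.06 labelled rec11 deletion and 4.92 in rec10-109. By chromosome the first map gave 3.03 on I, 2.67 on II and 0.52 on III, and the second 5.01, 5.16 and 4.12. The ade6 site, in a gene that serves as a strain marker, stood at -0.12 in rec10-109 where the other map had 3.32. Breaks were lower in rec10-109 between mei2 and omt2 by -1.90. They were higher in rec10-109 near adh1 (III, 1589163 to 1591682; 6.09 against 0.35), between SPCPB1C11.02 and SPCPB1C11.03 (by 5.09), at dom34 (4.92), between oca2 and gnr1 (4.91) and at erg31 (4.84). The overall difference of 2.12 depended on array scale, since the rec10-109 array had the widest null distribution (SD 0.81 against 0.33). It was 1.29 after normexp correction, 0.25 after quantile normalization and -0.21 after division by the null SD, and the maps differed in time, with no wild-type break map among these arrays.

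Rec8 lay at the centromeres and Rec11 did not. Over 102 probes in the centromeres (I, 3751447 to 3790979; II, 1596711 to 1648234; III, 1064196 to 1143090) the median Rec8 ratio was 1.22, and the median Rec11 ratio -0.22. Rec8 stood at 1.47, 1.36 and 0.89 on centromeres I, II and III, and at 1.74 over 273 centromere probes that match several places. Of 12 Rec8 sites, the highest was in the centromere of chromosome II (1624700 to 1627570; 2.15), and others lay in the flocculin gene gsf2 (1.90) and between kgd1, a subunit of oxoglutarate dehydrogenase, and sul1 (1.76). The interval between kgd1 and sul1 held the highest of 27 Rec11 sites (II, 1883083 to 1884600; 1.79), followed by sites at duc1 (1.78), between msp1 and zfs1 (1.69), at mti2 (1.56) and at sib1 (1.54). Of the 27 Rec11 summits 17 lay in coding DNA (63.0%, near the 61.5% of probes there) and 10 between converging genes. Both subunits were low in long intergenic regions (-0.23 each), where the linear element proteins were high, with 0.29 for Rec27 replicate 1, 0.30 and 0.25 for Rec25, 0.22 for Rec10 (-0.22 turned) and 0.08 for Mug20. In the same regions Rec27 replicate 2 stood at -0.20 as labelled. Coding genes had 0.09 for Rec8, 0.08 for Rec11 and -0.06 for Rec27 replicate 1. Regions between converging genes had 0.20 for Rec11 and 0.25 for Rec27 replicate 1, those between diverging genes -0.28 for Rec8, -0.27 for Rec11 and 0.08 for Rec27 replicate 1, and those between tandem genes 0.13 for Rec27 replicate 1. Transfer RNA genes outside the centromeres stood at 0.24 on Rec27 replicate 1, at 0.04 for Rec12 and at 0.35 for Rec12 in the rec27 deletion. Centromere probes were also high on arrays of other proteins, with 0.96 for Rec27 in the rec8 deletion against -0.08 on Rec27 replicate 1, and 0.91 for Rec12 in the rec27 deletion against 0.24 in the wild type. Breaks stood there at 0.73 in the map labelled rec11 deletion and at -0.75 in rec10-109. The mating type region (II, 2114219 to 2133394, 56 probes) was high for Rec27 replicate 1 (0.78), Rec25 (0.83 and 0.76) and Mug20 (0.65). Within 100 kb of the ends of chromosomes I and II the map labelled rec11 deletion stood at 0.62 and Rec27 in the rec8 deletion at 0.50.

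Among the gene lists, highly transcribed metabolic genes carried signal on most arrays. The 17 genes of glycolysis and high transcription had a median of 0.75 on Rec27 replicate 1, 0.91 and 0.66 on Rec25, 0.92 for Mug20, 1.34 and 1.24 for Rec12-Y98F and 2.33 for rec10-109 breaks, each above 10000 random gene lists. Rec27 in the rec8 deletion stood at -0.12, at percentile 11.9, with 0 of 17 genes above 1, and Rec11 at 0.10, at percentile 79.7. Within the list tdh1, a glyceraldehyde phosphate dehydrogenase gene (II, 2807595 to 2809051), had 2.53 and 2.49 on Rec25 and 4.50 in rec10-109 breaks, and adh1 (III, 1591292 to 1592889) had 1.13 on Rec27 replicate 1 and 4.90 in rec10-109 breaks. The 10 histone genes had 0.80 on Rec27 replicate 1 and 2.14 in rec10-109 breaks, with hhf3 at 4.71 in the latter. The 15 nitrogen starvation genes had 0.55 and 2.37, with isp7 at 1.64 on Rec27 replicate 1 and 0.13 in the rec8 deletion. The 15 stress response genes had 0.27 on Rec27 replicate 1 and 0.97 in rec10-109 breaks, with hsp16, a small heat shock protein gene, at 5.63 in the latter. The 135 ribosomal protein genes had 0.15 on Rec27 replicate 1 and -0.20 in the rec8 deletion. The 25 genes of meiotic recombination and the linear elements had -0.19 on Rec27 replicate 1 (percentile 0.66), with percentiles of 54.6 for Rec27 in the rec12 deletion, 98.1 in the rec8 deletion and 50.1 and 20.7 for Rec25. On Rec27 replicate 1 the medians were -0.11 for the 13 cohesin genes, -0.16 for the 16 middle meiotic genes, and 0.16 each for the 13 mitotic cell cycle genes and 12 genes of meiotic entry. The 9 strain markers had 0.19, with ade6 (III, 1316281 to 1318035) at 2.62 on Rec27 replicate 1, -0.03 in the rec8 deletion, 2.19 for Rec12 and 0.21 for Rec12 in the rec27 deletion. On Rec27 replicate 2 as labelled the glycolysis list stood at -0.67, the histone list at -0.38 and the nitrogen starvation list at -0.19.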

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

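No comparison in this part was chosen after the result was seen, but the 158 sites it uses were defined from Rec27 replicate 1 after the data were seen. The difference between Rec12-Y98F and wild-type Rec12 at the 158 Rec27 sites was picked out because it ran in opposite directions at the times sampled. The 3 h array was lower than the wild type by a median of -0.35 (122 sites lower, 36 higher), and the 4 h array was higher by a median of 0.0232 (75 lower, 83 higher). The 4 h array exceeded the 3 h array by a median of 0.39, above the range of random site sets (-0.04 to 0.11), which describes these arrays alone. The Rec25 replicates differed by a median of 0.37 at the same sites, close in size to the 0.39 and the -0.35. No p was given, since each time had 1 array and the wild-type array came from 3.5 h. The 4 h median difference from the wild type lay within the range of random site sets.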

How the results depend on the processing

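The tests that read Rec27 replicate 2 turned, cross the pairing, join the block to the GC trend, take reference sites from other arrays or replicates, or apply the outlier marks to the input signals were chosen after the results were seen; the other alternatives were fixed before. Of 860 values for 93 results, 595 kept their direction and their side of the threshold or stayed within the spread. For counts this meant a set ratio to the main value. The other 265 did not, and 6 of those had the opposite sign. Where no cause is named below, the cause was not tested. With the sign turned, Rec10 at Rec27 sites stood at -0.71, Rec27 replicate 2 at 1.79 and its r with replicate 1 at 0.695, which follows from turning the sign. Slide as a random block could not be estimated and was not run, a filter on saturated spots moves nothing with 0 saturated probes, and deleted genes have no value under the dim filter or in the series matrix. Signal over background limits how far a loss of DNA can be measured: the rec27 gene in its deletion went from -10.64 to -1.85 under normexp, whose offset raises the lowest signals, and the rec11 gene from -0.05 to 0.065.

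Turning Rec27 replicate 2 took the windows called from 0 to 321 for Rec27 against Rec25 and from 0 to 481 for the rec8 deletion. Leaving out 1 replicate at a time gave 0 to 1585, 0 to 912 and 0 to 831 windows for Rec25, the rec12 deletion and the rec8 deletion as labelled, and 195 to 522, 4 to 15 and 421 to 704 in the turned reading, with the lone array assumed to vary like the others. In the turned reading, normexp and division by the null SD each left 0 windows for Rec27 against Rec25 and 0 for the rec8 deletion. Quantile normalization left 5 (1 higher, 4 lower, against 23 and 298) and 381 (150 and 231, against 189 and 292). Windows of 2 kb, which are fewer, gave 138 (7 and 131) and 148 (52 and 96). For the rec12 deletion, turned, the series matrix and the lack of an outlier filter gave 1 window each, against 0. Of the 20 windows named for each of the turned comparisons, 0 stayed called under normexp or division by the null SD, and quantile normalization kept 2 and 16.

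The replicate numbers do not show a pairing: residuals of same-numbered arrays correlated at 0.30 as labelled and at -0.13 turned, with 2 groups of 2. With the replicate block the turned reading gave 412, 7 and 609 windows for Rec25, the rec12 deletion and the rec8 deletion, and with the GC trend also removed 359, 1 and 474. The crossed pairing gave 477, 39 and 779 (345 higher, 434 lower). The block changed no other call, and as labelled each of these fits left 0 windows.

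Normexp moved the difference between break maps from 2.12 to 1.29, the overlap of sites from 81.0% to 69.2%, the r of Rec27 with Rec25 from 0.691 to 0.636 and the centromere difference of Rec8 and Rec11 from 1.44 to 1.15. Division by the null SD turned the difference between break maps to -0.21 and gave -0.84 for Rec12 in the rec27 deletion (-0.33). Quantile normalization gave 0.25 for the break maps, 3.13 for the centromeres, -0.91 for Rec12 in the rec27 deletion and -0.14 for the rec12 deletion (0.30). The series matrix and the lack of an outlier filter gave r = 0.727 each, Spearman correlation 0.523, and leaving out either Rec25 replicate 0.661 to 0.694. Sites at 6 null SDs numbered 82, with an overlap of 93.9%, and gave -0.63 for Rec12 in the rec27 deletion, 1.32 for Rec12-Y98F (0.79) and 2.42 for the linear element proteins less the cohesins (1.66). The top 3% of probes gave an overlap of 62.9% and summits within 1 kb 72.8%. Without a replicate, 0 to 158 Rec27 sites were called and the overlap lay between 76.6% and 81.0%. Both Rec27 replicates averaged as labelled gave 33 sites, 2.57 for the linear element proteins, 1.41 for Rec12-Y98F, -0.007 for Rec12 in the rec27 deletion, 1.57 for the break maps and 0.41 for the rec8 deletion (-0.97). Those sites are left where the opposed replicates did not cancel, so their values do not test the results. Replicate 2 turned gave, averaged with replicate 1 and alone, 294 and 339 sites, 1.14 and 1.07 for the linear element proteins and 0.43 and 0.35 for Rec12-Y98F. The overlap was 71.1% for replicate 2 turned alone, and Rec25 sites gave 1.26 for the linear element proteins. Among the other results 447 values stayed the same, 161 moved and 5 had the opposite sign. A further 13 grew stronger and 23 weaker, which for counts means a change beyond a set ratio.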

Other observations

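Of the tests in this part, those of GC content and of the share of outlier-marked spots were written before the result was seen. The other tests were chosen after it, as were the intervals beside the values. For the dye channels and the rec11 input the interval is the value plus and minus the SD over the other arrays. The other intervals are 95% intervals from 2000 bootstrap draws of the sites. A set of places carried Rec12 in the rec27 deletion and Rec27 in the rec8 deletion together. Between SPBPB2B2.06c and SPBPB2B2.07c the arrays stood at 3.37 and 5.62, at pho84 at 3.54 and 5.35, between pcs2 and hsr1 at 3.28 and 5.33, and between mei2 and omt2 at 2.79 and 4.10. Wild-type Rec12 had 0.27, 0.93, 1.04 and 0.70 there. These places were picked as the largest gains of Rec12 in the rec27 deletion over the wild type, so that contrast follows from the choice. Wild-type arrays of other proteins could also be high there. Rec25 stood at 4.06 and 3.47 around SPBPB2B2.06c and SPBPB2B2.07c, and at 5.16 and 4.86 between pcs2 and hsr1. In mei2 itself Rec12 in the rec27 deletion had 1.77 and Rec12 in the wild type 0.49, and in isp3, a spore wall gene, 2.69 and 1.05. Summits of Rec12 sites lay in coding DNA in 18 of 61 cases in the rec27 deletion (29.5%), 23 of 131 in the wild type (17.6%), 8 of 19 for Rec12-Y98F at 3 h (42.1%) and 5 of 33 at 4 h (15.2%). The recombination gene rec7 carried Rec25 (2.06 and 1.64) and Mug20 (1.22) but little Rec27 (0.03 on replicate 1), and pex7 carried breaks in both maps (4.40 and 5.28). The leu1 gene had 1.32 on Rec27 replicate 1 and 1.18 for Mug20.

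The rec12 gene itself stood at 5.80 in the rec10-109 break map and 1.30 in the map labelled rec11 deletion. Its input was lower in rec10-109 by -1.95. A single rec12 probe (I, 1773732 to 1773791) was lost from the input of both break maps and of the 4 arrays of Rec12 protein, by -6.00 to -8.86, and stood between -0.15 and 0.39 on the arrays of other proteins, apart from the rec12 deletion (-12.00). Loss of a single probe was also seen without a Rec12 immunoprecipitate: another rec12 probe (I, 1773127 to 1773186) stood at -6.75 on Rec27 in the rec8 deletion and -7.21 on Rec25 replicate 1. Those arrays shared a slide and had the highest shares of flagged probes (18.5% and 19.1%), so their loss need not be of the same kind. Some genes outside the deleted ones were also low in both channels, among them tim8 (-5.20 in Cy3) and mrp11 (-5.17) on the rec8 deletion array, rpa43 (-4.50) and mrpl23 (-4.81) on Rec25 replicate 1, and mrpl44 on both. Probes of mitochondrial DNA had medians of -1.96 for Mug20 and -1.90 for Rec11.

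Rec27 replicate 2 ran opposite to replicate 1. A hypothesis is that its dyes were recorded the wrong way round. The Cy5 channel, labelled as immunoprecipitate, followed the pooled input of the other arrays more closely than the Cy3 channel by 0.256 in r (interval 0.178 to 0.334), whereas on 14 other arrays labelled the same way it followed less, by -0.283 to -0.0485, which is consistent with exchanged dyes. The Rec10 array, whose labels conflict, was left out (Cy5 0.851, Cy3 0.696). DNA of a strain without tagged Rec27 would carry no signal at Rec27 sites, but as labelled the array stood there at -1.79 (-1.93 to -1.54), outside random site sets (-0.06 to 0.05), and no biological explanation was tested.

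The array labelled rec11 deletion kept rec11 DNA. A label swapped with another array may be set aside for this series, since the lowest input over rec11 on the other 15 arrays was -0.21 (-0.30 to -0.11). An allele that leaves the coding DNA in place cannot be told apart, because 0 of 14 rec11 probes were lost and such an allele would leave no mark on them. A strain with working Rec11 could not be excluded either: across Rec27 sites the map correlated more with Rec27 in the rec8 deletion (rho = 0.852) than with Rec27 replicate 1 (0.647), and the interval of the difference (0.205, 0.105 to 0.315) spans the bound set for it. The same map correlated with wild-type Rec25 at 0.872 and 0.885, so the comparison did not separate a strain with Rec11 from one without it.

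Rec27 in the rec8 deletion kept a part of its sites and few on chromosome III, but wild-type Rec25 had a gap between III and I and II at the same sites too (1.49 against 2.98 and 1.01 against 2.52, beside 0.12 against 0.98). The gap alone therefore cannot be laid to the loss of Rec8. Rec27 replicate 1, which defined the sites, had 1.72 on III against 1.89 on I and II. Over windows in Rec27 sites, the deletion less wild-type Rec27 with replicate 2 turned had medians of -1.02 on III, -0.50 on I and -0.36 on II. GC content of the probes does not account for the gap, since sites on III stayed below those on I and II by -0.90 (-1.38 to -0.51) after removal of the GC trend, against -0.85 before. Loss of spots to the outlier filter does not account for it either, since with those spots put back III stayed lower by -0.87 (-1.39 to -0.53). Whether faults traced by the marks raised the kept sites cannot be told apart, as marked probes made up 28.9% at the 57 kept sites and 20.0% at the other 101, a difference of 8.90 points (3.33 to 14.4) that spans the bound of 10. A candidate explanation is that a part of the sites does not depend on Rec8. Rec12 in the rec27 deletion correlated with Rec27 in the rec8 deletion at 0.705 and with Rec27 in the rec12 deletion at 0.407. The interval of the difference (0.298, 0.194 to 0.412) also spans its bound. Wild-type Rec25 correlated with Rec12 in the rec27 deletion at 0.526 and 0.512, and with Rec27 in the rec8 deletion at 0.771 and 0.770. The comparison cannot decide dependence on Rec8, since only Rec27 in the rec8 deletion came from a strain without rec8 and wild-type Rec25 shared the pattern. With 1 array per strain the explanation stays open.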
